A study of Mus musculus with 20 samples.

How the data were processed

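The study measured RNA in lung tissue of C57BL/6 mice, a common inbred laboratory strain, with the MA07 array, a set of cDNA clones read 1 array per mouse. Total RNA was extracted with acid guanidinium thiocyanate, phenol and chloroform and copied into radioactive cDNA by reverse transcription, per the labels' protocols. The 20 mice were assigned to 4 groups of 5 from the treatment named in each label: untreated, flaxseed diet, thoracic radiation, and both. The radiation dose was 13.5 Gy with tissue taken 48 hours later, and the diet held 10% flaxseed for 21 days, per the labels. The labels give each array its own mouse number, so the 5 arrays of a group were taken as 5 animals. The numbers run on through the groups and pair no mice. The diet of the mice without flaxseed, the sex and age of the mice, and any batch of membranes, hybridisation or scanning are not given in the sources used here.

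The deposited array tables hold the median signal intensity and the median background intensity of each of 9600 spots, per the file headers. These are linear intensities from 1 colour, with the background not subtracted. The scanner, the image software and any spot filter are not given in the sources used here. The authors also deposited 1 table of processed intensities for the 20 arrays, which carries no description of its making. Set against the array tables, 98.1% of its values equalled the signal minus the background divided by the median of that difference on the array, within a relative tolerance of 0.001. The other 3558 values, 1.85% of all, were the constant 0.002, and why these spots were given it is unknown. Its columns had medians between 0.999 and 1, its scale was linear, and its values were not centred by clone. It was used as an alternative only, and each of its columns belonged to 1 of the 20 arrays.

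Signal intensities were corrected for background with normexp in limma 3.58.1 under R 4.3.3, with an offset added. The rule set the offset at 0.1 times the median signal where that lay under 500, and the median signal over all spots and arrays was 162.5, which gave an offset of 16.3. Corrected intensities were put on the log2 scale and quantile normalised between the 20 arrays. All 9600 clones were tested, and none was filtered out. For each clone, limma's lmFit and eBayes fitted 1 mean per group to all 20 arrays, which gave 16 residual and 6.08 prior degrees of freedom. Contrasts were taken for 8 comparisons: 5 between pairs of groups, the radiation effect averaged over the diets, the diet effect averaged over radiation, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all clones within a comparison, and a clone was called changed at an adjusted p under 0.05. Fold changes are differences of log2 values that include the offset, which understates the changes of dim clones. The number of arrays limits the precision: the median half-width of a clone's 95% confidence interval was 0.46 on the log2 scale for a pair of groups and 0.33 for an averaged effect.

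The fit was tested on simulated arrays with 200 changed clones among 9600. Values were drawn on the normalised scale, with noise independent between clones and of the same spread on all arrays. The real arrays had residual SDs from 0.271 to 0.459 log2 units. The shares below hold for noise of the simulated kind, and the share of false calls does not test the real noise. For radiation in mice without flaxseed it recovered 14.6% of 1.5-fold, 68.4% of 2-fold and 99.5% of 4-fold changes, and 4.95% of its calls were false. For radiation averaged over the diets it recovered 49.6% of 1.5-fold and 94.0% of 2-fold changes. For flaxseed in unirradiated mice the shares were 15.0% of 1.5-fold and 70.8% of 2-fold changes. For flaxseed averaged over radiation they were 48.7% and 95.5%. For the interaction, simulated as changes in mice given both treatments alone, they were 3.13% and 25.4%, with 94.5% of 4-fold changes recovered.

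The files identify clones by a serial ID and do not pair the IDs with gene names. None of the 9600 IDs matched a gene, locus tag, synonym or transcript in the mouse RefSeq table used here (assembly GRCm38.p6). The 25 gene lists fixed before the data were examined, which covered pathways and cell types of the lung, could therefore not be tested, and neither could the list scores per mouse or the alternatives that belong to them. The rule for naming genes, also fixed then, took the largest increases and decreases by log2 fold change among called clones of a pair of groups, and the smallest p for averaged effects, the interaction and any comparison with fewer than 5 calls. Without gene names the same rule was applied to clone IDs and cut to at most 2 that rose and 2 that fell per comparison, and to 1 in each direction where no clone was called.

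The IDs number the spots in 384 square blocks with 5 spots to a side, and the order of the file places these blocks on a grid of 120 columns and 80 rows. This layout was worked out from the IDs and the file order and is not stated in the files. No pair of arrays held identical values, and the highest correlation between 2 arrays across clones was 0.974.

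The alternatives set before the data were examined were plain background subtraction, no background correction, normexp with no offset and with 4 times the offset, median scaling, cyclic loess, Z-scores of log10 intensity, the authors' processed table, filters that kept the 4800 or the 7200 brightest clones, an intensity trend with robust variances, array weights, a fit to only the groups compared, a threshold of 0.1, and leaving out each mouse. A batch as a block was planned but not run, because the files name no batch. Chosen after seeing the data were removal of each array's local median over a window of 15 by 15 spots, removal of the median of each of the 25 positions within a block, the authors' table with its constant as missing, a term for the level of background, the log2 median signal as a covariate, and a fit without the 2 arrays of lowest residual spread. The tests of diet on the first component within each radiation group were also chosen then. Comparisons of single values used exact permutation tests over all arrangements of the mice, or permutation tests with 100000 resamples where groups held 10 arrays.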

Results

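Lung RNA was profiled in 20 C57BL/6 mice, 5 in each of 4 groups: untreated, fed flaxseed, given thoracic radiation, or given both. Flaxseed, the seed of Linum usitatissimum, is rich in lignans and alpha-linolenic acid, and made up 10% of the diet for 21 days. Radiation was a dose of 13.5 Gy to the thorax, and lungs were taken 48 hours later. Each mouse was read on its own membrane with 9600 spotted clones. Median spot signals ranged from 97.4 to 336 intensity units over the 20 arrays, and median backgrounds from 13.4 to 46.7 units. On each array 86.9% to 93.4% of spots exceeded 2 times their background, and 36 to 113 spots lay at or below it. The log2 median signal was 7.50 ± 0.50 (SD) on the 10 irradiated arrays and 7.18 ± 0.34 (SD) on the 10 unirradiated arrays (two-sided permutation test, p = 0.105). Arrays of the same group correlated across clones with a mean r between 0.925 and 0.962 per array. The clones carry serial IDs that the files do not pair with gene names, so they are given by ID.

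The largest component of variation between arrays, 16.8% of the variance, followed irradiation. Scores on it averaged 14.9 ± 8.09 (SD) in the 10 irradiated arrays and -14.9 ± 8.06 (SD) in the 10 unirradiated arrays, and a two-sided permutation test gave p = 2e-05. On the same component, flaxseed-fed mice averaged -21.1 ± 3.92 and untreated mice -8.69 ± 5.86 (SD, n = 5) without overlap, a difference of -12.4 (two-sided exact permutation p = 0.00794, the smallest the design allows). Mice given both treatments averaged 10.4 ± 3.27 and irradiated mice 19.4 ± 9.32 (SD, n = 5), a difference of -8.91 (exact permutation p = 0.0873), and the mean of both differences was -10.7 (exact permutation p = 0.00101, diets exchanged within irradiation). With diets exchanged regardless of irradiation, where the radiation effect adds to the spread, it gave p = 0.169 (two-sided permutation test). The tests within irradiation were chosen after seeing the data. Within arrays of lower background the differences in unirradiated and irradiated mice were -15.4 and -6.83, and within those of higher background -13.2 and -8.28, over groups of 1 to 4 mice. Mean residual variances were 0.186 in flaxseed-fed and 0.138 in untreated mice, and 0.185 in irradiated and 0.136 in doubly treated mice. The part of this unequal noise in the differences on the component was not tested.

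The first comparison asked what radiation changed in mice without flaxseed. In irradiated lungs 43 clones fell and 25 rose against untreated lungs, by a median of 2.19-fold. Background was unbalanced here, since 4 of 5 irradiated but 1 of 5 untreated arrays were of higher background. With a term for it 30 clones were called, 26 of them among these calls in the same direction. The clone gene7016 fell by 3.42 on the log2 scale (SE 0.61, limma adjusted p = 0.00886), from 12.58 ± 0.56 to 9.15 ± 1.40 log2 intensity (SD, n = 5), and no irradiated mouse overlapped an untreated one. The clone gene8916 fell by 3.15 (SE 0.67, adjusted p = 0.0337), from 9.01 ± 1.47 to 5.86 ± 0.53 (SD, n = 5), with overlap between the groups. Among the clones that rose, gene3840 increased by 1.25 (SE 0.29, adjusted p = 0.048), from 5.06 ± 0.44 to 6.31 ± 0.33 (SD, n = 5). Its spot exceeded the background on 4 of 5 untreated arrays and on all irradiated ones, and its log2 fold change depended on the background correction: it was 0.64 with 4 times the offset, 2.08 with no offset and 3.70 with plain subtraction. The clone gene0744 rose by 1.17 (SE 0.26, adjusted p = 0.0389), from 7.51 ± 0.57 to 8.68 ± 0.26 (SD, n = 5). Leaving out single mice in turn gave between 13 clones (without untreated mouse 5) and 108 clones (without irradiated mouse 5), where 59 rose and 49 fell, while falls outnumbered rises in the other 19 cases. The calls of gene3840, gene0744 and gene8916 were lost on leaving out any of 14, 7 and 7 of the 20 mice, whereas that of gene7016 held in each case, with adjusted p up to 0.0453. Other processing ended the call of gene3840 in 11 of 17 alternatives (adjusted p from 0.00129 to 0.417), that of gene0744 in 7 of 19 (0.0242 to 0.105) and that of gene8916 in 4 of 18 (0.00678 to 0.313), and that of gene7016 in none of 19.

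The second comparison asked what radiation changed in mice fed flaxseed. Against flaxseed alone, lungs of mice given both treatments had 102 clones that fell and 107 that rose, by a median of 2.03-fold. The clone gene7016 again had the strongest decrease and fell by 3.06 on the log2 scale (SE 0.61, limma adjusted p = 0.0103), from 13.17 ± 0.81 to 10.11 ± 1.41 log2 intensity (SD, n = 5). It was followed by gene1185, which fell by 2.65 (SE 0.38, adjusted p = 0.00135), from 10.93 ± 0.72 to 8.27 ± 0.82 (SD, n = 5). The largest increases among called clones were those of gene3160, up 1.42 (SE 0.31, adjusted p = 0.018) from 9.15 ± 0.86 to 10.57 ± 0.15 (SD, n = 5), and gene9436, up 1.38 (SE 0.25, adjusted p = 0.00744) from 13.69 ± 0.39 to 15.08 ± 0.31 (SD, n = 5). The rise of gene9436 depended on the normalisation, since it was 0.67 with adjusted p = 0.291 under cyclic loess (0.00249 to 0.527 over 19 alternatives). The balance of calls did too: 51.2% of them were increases after quantile normalisation, 82.5% of 577 after median scaling, 79.2% of 318 in the authors' processed table and 32.9% of 143 after cyclic loess. With single mice left out they were 39.4% to 53.7% of between 82 and 237 calls, with 82 without flaxseed mouse 2 and 110, 125, 116 and 134 without mice 1, 3, 4 and 5 given both treatments. Without the 2 arrays of lowest residual spread, both of mice given both treatments, 44 clones were called, and gene7016, gene3160 and gene9436 no longer passed. Their log2 fold changes were then -3.01 (SE 0.73, adjusted p = 0.0706), 1.32 (SE 0.37, adjusted p = 0.107) and 1.31 (SE 0.30, adjusted p = 0.0577), so that relative to their size the SEs grew more than the folds shrank. These were the highest adjusted p over the alternatives for gene7016 and gene3160, whose lowest were 0.00197 and 0.00123.

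**Figure D1:**
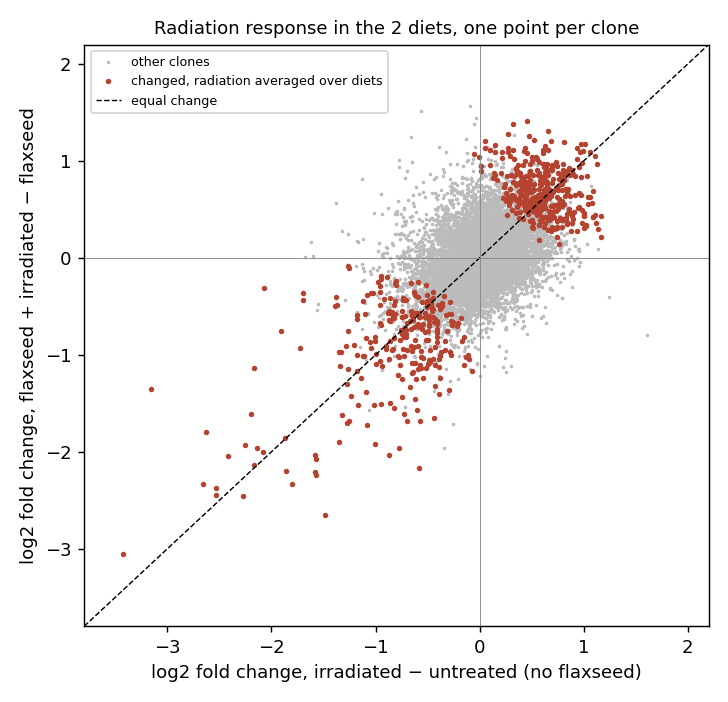
Log2 fold change of each of 9600 clones after radiation without flaxseed (x axis) and with flaxseed (y axis), with the 626 clones changed by radiation averaged over the diets in red and the line of equal change dashed. Across all clones r was 0.486, and the strongest falls lie near the dashed line.

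The radiation fold changes in the diets rest on different mice and could be set against each other. Across all 9600 clones the radiation fold changes without and with flaxseed correlated with Pearson r = 0.486 and Spearman rho = 0.413, a relation across clones, which are not independent replicates. Of the 68 clones called without flaxseed, 59 had a fold change of the same sign with it, and of the 209 called with flaxseed, 187 had the same sign without it, where 63.2% of all 9600 clones had the same sign in both diets. Changes were larger in the diet in which the clones were called, as picking clones by a threshold in that diet gives by itself. These sizes therefore show no difference between the diets. The 68 had a median absolute log2 fold change of 1.13 without flaxseed and 0.554 with it. The 209 had 1.02 with flaxseed and 0.498 without it. In both diets 25 clones were called. Decreases called in both diets numbered 19, where independent lists of these lengths would share 0.457, and increases called in both numbered 6, where they would share 0.279. The calls of both diets use the same estimate of each clone's spread, from all 20 arrays, so the lists are not independent. How much of the sharing comes from that was not tested. No clone passed for the interaction, which tests the difference between the responses.

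Averaged over the diets, radiation changed 626 clones, of which 266 fell and 360 rose, by a median of 1.58-fold. The falls were larger than the rises: 67 clones fell and 9 rose by 2-fold or more. The lowest log2 fold change was -3.24 and the highest 1.09. The smallest p among decreases belonged to gene7221, which fell by 2.45 (SE 0.22, limma adjusted p = 1.45e-06), from 13.44 ± 0.47 in the 10 unirradiated mice to 10.99 ± 0.57 log2 intensity in the 10 irradiated mice (SD). The clone gene4847 fell by 2.50 (SE 0.25, adjusted p = 6.6e-06), from 14.29 ± 0.38 to 11.79 ± 0.76 (SD), and for both clones the 10 irradiated mice lay below all 10 unirradiated ones. The smallest p among increases belonged to gene1249, which rose by 1.07 (SE 0.13, adjusted p = 5.26e-05), from 6.73 ± 0.30 to 7.80 ± 0.35 (SD) without overlap, and to gene4588, which rose by 0.86 (SE 0.12, adjusted p = 0.000217), from 6.47 ± 0.24 to 7.33 ± 0.28 (SD). These 4 calls held with each mouse left out in turn. Those of gene7221 and gene4847 also held under all 18 processing alternatives, and those of gene1249 and gene4588 under the 17 that tested them, since the filter for the 4800 brightest clones left both out.

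**Figure D2:**
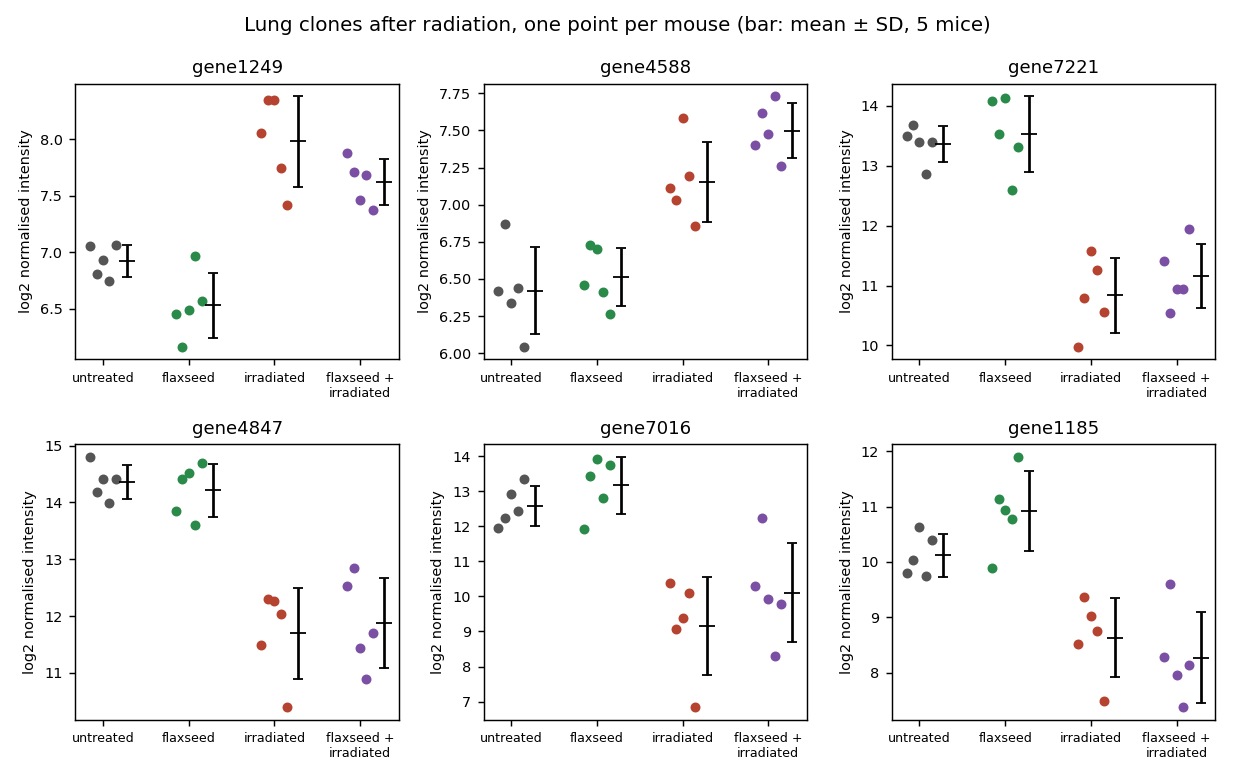
Log2 normalised intensity (y axis) of 6 clones changed by radiation in the 4 groups (x axis), 1 point per mouse, with the mean and SD of 5 mice as a bar beside the points. In gene7221 and gene4847 all 10 irradiated mice lie below all 10 unirradiated mice, and in gene1249 they lie above.

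Clones changed by radiation were more frequent among bright spots. In the dimmest 10% of clones by mean log2 intensity 6 rose and 2 fell, and in the brightest 10% 88 rose and 61 fell, of 960 clones each. Of the 67 clones that fell by 2-fold or more, 29 (43.3%) belonged to the brightest 10%. The changed clones were also spread unevenly over the membrane. In the upper 8 of the 16 rows of blocks 268 clones rose and 87 fell, and in the lower 8 rows 92 rose and 179 fell. With each array's local median over the membrane removed, 684 clones were called, and 488 of the 626 were among them in the same direction. Increases made up 57.5% of the calls after quantile normalisation, 70.7% of 923 after median scaling, 72.6% of 693 in the authors' processed table and 46.6% of 571 after cyclic loess. Without the 2 arrays of lowest residual spread 335 clones were called, and with the log2 median signal as a covariate 403.

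**Figure D3:**
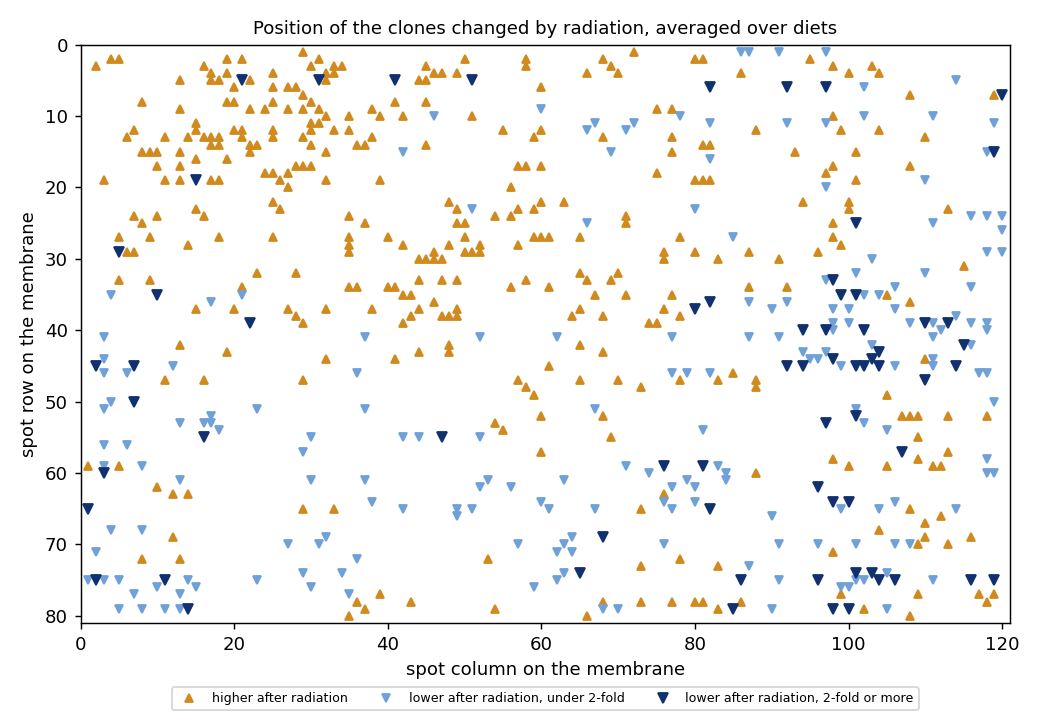
Spot column (x axis) and row (y axis) on the membrane of the 626 clones changed by radiation averaged over the diets. Upward triangles mark the 360 clones that rose and downward triangles the 266 that fell, with the 67 falls of 2-fold or more in dark blue, and increases lie mostly in the upper rows.

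The third comparison asked what flaxseed changed in unirradiated mice. No clone passed an adjusted p under 0.05 in limma, and 869 clones had an unadjusted p under 0.05, where 480 are expected by chance. Without untreated mouse 2, 2 clones passed, and without flaxseed mouse 5, 3 clones did. The smallest p belonged to gene8290, at 6.26 ± 0.32 log2 intensity with flaxseed and 7.29 ± 0.36 without (SD, n = 5), a difference of -1.04 (SE 0.18, limma adjusted p = 0.0758). Its adjusted p fell to 0.0237 with the membrane trend removed and to 0.034 with the median of each block position removed, and it ranged up to 0.256 over 18 alternatives. The smallest p among positive differences belonged to gene0743, at 7.93 ± 0.13 and 7.10 ± 0.35 (SD, n = 5), a difference of 0.83 (SE 0.16, limma adjusted p = 0.155).

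The fourth comparison asked what flaxseed changed in irradiated mice. No clone passed in limma, and 580 had an unadjusted p under 0.05 against 480 expected. Without irradiated mouse 5, 6 clones passed, of which 2 were higher and 4 lower with flaxseed, and 1 clone passed without untreated mouse 1 or without mouse 5 given both treatments. The clone with the smallest p, gene5360, was at 10.62 ± 0.38 log2 intensity in mice given both treatments and at 9.18 ± 0.47 in mice given radiation alone (SD, n = 5), a difference of 1.43 (SE 0.25, limma adjusted p = 0.0837). In untreated and flaxseed-fed mice the same clone was at 11.09 ± 0.47 and 11.37 ± 0.30 (SD, n = 5). It passed with no background correction (adjusted p = 0.0494), among the 7200 brightest clones (0.0424) and among the 4800 brightest (0.0347), and its adjusted p reached 0.254 over 19 alternatives. The clone gene7396 was at 6.61 ± 0.32 and 7.61 ± 0.41 (SD, n = 5), a difference of -1.004 (SE 0.21, limma adjusted p = 0.223).

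Lungs of mice given both treatments were also compared with untreated lungs, and 13 clones fell and 4 rose. Leaving out single mice gave 3 to 21 clones, with 7, 8, 6 and 3 without untreated mice 2, 3, 4 and 5, 11 without flaxseed mouse 3, 10 without irradiated mouse 3, and 3, 4 and 6 without mice 3, 4 and 5 given both treatments. The clone gene4847 fell by 2.48 on the log2 scale (SE 0.36, limma adjusted p = 0.0026), from 14.36 ± 0.30 to 11.88 ± 0.80 log2 intensity (SD, n = 5), and gene8946 fell by 2.24 (SE 0.41, adjusted p = 0.0241), from 13.94 ± 0.46 to 11.70 ± 1.12 (SD, n = 5). The clone gene3837 rose by 1.09 (SE 0.20, adjusted p = 0.0272), from 7.55 ± 0.31 to 8.64 ± 0.30 (SD, n = 5), and gene4588 rose by 1.08 (SE 0.17, adjusted p = 0.00761), from 6.42 ± 0.30 to 7.50 ± 0.18 (SD, n = 5). The calls of gene3837 and gene8946 were lost on leaving out any of 6 and 5 of the 20 mice, and in 4 and 5 of 19 processing alternatives (adjusted p from 0.00773 to 0.101 and from 0.00398 to 0.067). With plain background subtraction 3 clones were called, and with array weights 44.

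Averaged over radiation, flaxseed changed no clone at an adjusted p under 0.05 in limma, with 867 at an unadjusted p under 0.05 against 480 expected, and 3 clones passed without irradiated mouse 5. The smallest p of each direction belonged to gene5360, with a difference of 0.86 (SE 0.18), and gene7867, with a difference of -0.66 (SE 0.14), and both had an adjusted p of 0.21. The interaction asked whether the radiation response differed between the diets. No clone passed in limma, and 578 had an unadjusted p under 0.05. Without untreated mouse 3 or without mouse 2 given both treatments, 1 clone passed. For gene6081 the log2 fold change with radiation was -0.65 without flaxseed and 0.99 with it, a difference of 1.63 (SE 0.30, adjusted p = 0.0992), with means of 8.10 in untreated, 7.12 in flaxseed-fed, 7.46 in irradiated and 8.11 log2 intensity in doubly treated mice. For gene9246 it was 0.24 without flaxseed and -1.04 with it, a difference of -1.28 (SE 0.28, adjusted p = 0.301), with means of 7.70, 8.46, 7.94 and 7.43 in the same order. Its adjusted p was 0.0478 with the membrane trend removed and up to 0.951 over 18 alternatives. The highest came from the authors' processed table, where the direction turned to 0.67, and with the constant of that table as missing it was -1.37 (adjusted p = 0.255). The median half-width of the unadjusted 95% interval for an interaction was 0.66 on the log2 scale. In simulated arrays the fit recovered 25.4% of 2-fold and 94.5% of 4-fold differences between the responses.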

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

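The tests of the radiation calls against differences between arrays were chosen after the calls had been seen, and the other splits of the mice before. Over 108 groups of 5 values, taken from array measures and from the clones given by ID, 6 held a mouse whose gap to the nearest of the others was large against the range of the group, where chance gives 5.4. The median background of untreated mouse 1 was 35.8 intensity units, against 15.8 to 18.6 in the other 4 untreated mice. The clone gene8916 was at 6.45 log2 intensity in untreated mouse 3 and at 9.24 to 10.19 in the others. In untreated mouse 4, gene3840 was at 4.30, against 5.07 to 5.36. In untreated mouse 2, gene0743 was at 7.72, against 6.85 to 6.99. In untreated mouse 5, gene3837 was at 7.03, against 7.58 to 7.81. In mouse 4 of the group given both treatments, gene9246 was at 8.18, against 7.10 to 7.37.

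The 626 clones changed by radiation averaged over the diets were weighed against technical differences between arrays. With the log2 median signal of the array as a covariate, 360 of them were still called in the same direction. With each array's local median over the membrane removed 488 were, and with the median of each position within a block removed 419 were. With a term for the 10 arrays of higher background 499 were, so that none of these differences alone accounts for the averaged calls as a whole. For irradiated against untreated mice background was unbalanced, and with that term 30 clones were called, 26 of them among the 68 in the same direction. All 68 kept their direction with an unadjusted p under 0.05 in limma, but background stays open for part of these calls. The direction of the calls differed between positions within a block. At position 2, 29 fell and 3 rose, and at position 8, 3 fell and 32 rose. Median log2 fold changes by position ran from -0.123 to 0.151, and why they differ was not tested. Fitted apart, the 10 arrays of lower background called 7 clones and the 10 of higher background 40, and 7 of the 7 and 38 of the 40 had the same direction in the arrays of the other level. A response to radiation remains the open explanation as a hypothesis, and a batch that the labels do not give was not tested.

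Other splits of the same mice were fitted for each comparison, 100 splits with the real one included. For pairs of groups the fit held only their 10 arrays. For irradiated against untreated mice the real split called 51 clones and the highest other split 3, so that 1 split of 100, the real one, reached the real value. This is the fewest that 100 splits allow, and the 8 comparisons were not corrected for. Chance is thus argued against but not excluded. The same 1 of 100 was found for both treatments against flaxseed (168 clones, highest other 2), for both against untreated (22, highest other 2) and for radiation averaged over the diets (626, highest other 3). Where no clone was called, the number at an unadjusted p under 0.05 was compared. For flaxseed against untreated mice it was 828, reached by 2 of the 100 splits with 865 as the highest other. This passes 0.05 taken alone, but another split exceeded it and the 8 comparisons were not corrected for, so chance is not excluded. For both treatments against irradiated mice it was 606, reached by 17 splits, with 835 as the highest other. For diet averaged over radiation it was 867, reached by 5 splits, with 1045 as the highest other. For the interaction it was 578, reached by 27 splits, with 1431 as the highest other. In these last comparisons chance is not excluded either. Splits for the interaction exchanged irradiated and unirradiated mice within a diet, which puts part of the radiation effect into the contrast.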

How the results depend on the processing

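The alternatives without the 2 arrays of lowest spread, with the membrane trend or block positions removed, with the background term or brightness covariate, and with the constant as missing were chosen after seeing the data, and the others before. The interaction of gene9246, not called at -1.28, turned to 0.67 in the authors' table (adjusted p = 0.951) and was -1.37 there with the constant as missing. No other clone given by ID and no score difference turned. The median log2 fold change of all clones moved by less than 0.1, but bringing the arrays to a common level keeps it small by itself. Radiation averaged over the diets called 626 clones and kept within 1.5 times of that except with the threshold at 0.1 (1100), with array brightness as a covariate (403) and without the 2 arrays of lowest spread (335). Increases led decreases by 360 to 266, and decreases led under cyclic loess (305 to 266), with block positions removed (240 to 234) and with the brightness covariate (208 to 195). It gave 448 to 685 with single mice left out. Irradiated against untreated mice called 68 clones, against 22 with plain background subtraction, 20 in the authors' table (2 of them increases), 43 among the 4800 brightest clones, 39 with block positions removed, 30 with the background term, 33 without the 2 arrays and 193 at 0.1. Both treatments against flaxseed called 209, against 113 with plain subtraction, 123 with the brightness covariate, 44 without the 2 arrays, 577 with median scaling, 318 in the authors' table, 383 there with the constant as missing, 352 with array weights and 411 at 0.1. Of the 577 with median scaling, 176 were among the 209 in the same direction. Both treatments against untreated mice called 17, against 3 with plain subtraction, 8 with 4 times the offset, 5 in the authors' table (2 increases), 7 with the membrane trend removed, 8 without the 2 arrays, 44 with array weights and 29 at 0.1. The 4 comparisons without calls gained few: flaxseed against untreated mice had 1 with the membrane trend removed, 1 with block positions removed and 1 at 0.1. Both treatments against irradiated mice had 1 without background correction, 1 among the 7200 and 2 among the 4800 brightest clones, and 1 at 0.1. The interaction had 2 with the membrane trend removed and 2 at 0.1, and diet averaged over radiation had 0 under each alternative other than leaving out a mouse. Filters test fewer clones and fits without mice hold fewer arrays; for the other changes the cause was not tested.

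With single mice left out, irradiated against untreated gave 13 to 108 clones. It gave 37, 32, 33 and 13 without untreated mice 1, 2, 4 and 5, 37 without flaxseed mouse 5, 20, 40, 31, 33 and 108 without irradiated mice 1 to 5, and 42 without mouse 1 or mouse 5 given both treatments. Both treatments against flaxseed gave 82 to 237, with 82 without flaxseed mouse 2 and 110, 125, 116 and 134 without mice 1, 3, 4 and 5 given both. Both against untreated gave 3 to 21, with 7, 8, 6 and 3 without untreated mice 2, 3, 4 and 5, 11 without flaxseed mouse 3, 10 without irradiated mouse 3, and 3, 4 and 6 without mice 3, 4 and 5 given both. Flaxseed against untreated gave 0 to 3 (2 without untreated mouse 2, 3 without flaxseed mouse 5), both against irradiated 0 to 6 (6 without irradiated mouse 5, 1 without untreated mouse 1 or mouse 5 given both), diet averaged over radiation 0 to 3 (3 without irradiated mouse 5), and the interaction 0 to 1 (1 without untreated mouse 3 or mouse 2 given both). Of the values of single clones and of the score under the alternatives, 470 kept their direction and side of the threshold, 1 changed direction, 43 lost their call and 16 gained one. Dim clones are limited by signal over background, as gene3840 shows, whose log2 fold of 1.25 (adjusted p 0.00129 to 0.417 over 17 alternatives) was 0.64 with 4 times the offset and 3.70 with plain subtraction. No paired analysis was possible because the mouse numbers run on through the groups.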

Other observations

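The tests in this part were chosen after the patterns had been seen, except the relabelling of diets over all clones, which was set before its result.

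The 67 clones that fell by 2-fold or more after radiation were not spread evenly over the 25 positions within a block. Position 21, the left end of the lowest row of a block, held 14 of them where 2.68 were expected (permutation test of the highest count, p = 5e-05). The test takes the clones as independent, and clones that follow each other, as the 14 do below, make this p too small. Other positions also held many: 10 at position 22, 8 at 24, and 7 each at 18 and 20. The checks of a single position below were made for position 21 alone. Signal spilling from brighter neighbours is argued against as the source of these falls, since 5.97% of the 67 clones touched a brighter clone of the same set, and none of the 14 did. The 483 neighbours outside the set had a median log2 fold change of -0.0995. Of these neighbours 27 were called lower, against 266 of all 9600 clones, so weaker spill onto them stays open. A shift of every spot at that position is argued against too, since the median log2 fold change of its 384 clones was -0.0443. The 14 clones followed each other from mouse to mouse within groups, with a median pairwise r of 0.437 where 1000 random sets of 14 clones gave at most 0.176, and 16 of their 91 pairs reached 0.7. Noise shared by the spots of a position was not tested as a source of this r. Whether some of them are one transcript, or DNA carried over between wells, cannot be told apart from separate transcripts that respond together, because this r lies between what each predicts and the clones have no names here.

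Flaxseed called no clone, yet a candidate pattern is that clones changed by radiation differ with flaxseed in the direction opposite to radiation. For each mouse a score was taken over the clones called for radiation without that mouse, 245 to 410 higher and 193 to 313 lower ones, as the mean log2 deviation of the higher clones minus that of the lower ones, divided by 2. It averaged -0.169 ± 0.109 in untreated, -0.378 ± 0.130 in flaxseed-fed, 0.320 ± 0.116 in irradiated and 0.220 ± 0.0414 in doubly treated mice (SD, n = 5). The difference with flaxseed was -0.209 in unirradiated mice (exact permutation p = 0.0238), -0.1003 in irradiated mice (exact permutation p = 0.119) and -0.155 averaged over both (exact permutation p = 0.00419), and the test of the unirradiated against the irradiated difference gave 0.109 (exact permutation p = 0.371). Single mice were then left out of the test only. The scores of the other mice were kept, so the mouse left out still helped to choose and centre their clones. On these terms the difference in unirradiated mice no longer passed without untreated mouse 1, 3 or 4 or flaxseed mouse 2 (-0.179, -0.197, -0.196 and -0.164, each with exact permutation p = 0.0556). That in irradiated mice ranged from -0.0594 without irradiated mouse 1 (exact permutation p = 0.206) to -0.125 without irradiated mouse 2 (exact permutation p = 0.0317), the only removal with which it passed, and the averaged one passed in each case (exact permutation p from 0.00154 to 0.00954). The arrays of higher background were 5 of 10 in both diets, but 1 of 5 untreated against 3 of 5 flaxseed-fed mice, and 4 of 5 irradiated against 2 of 5 doubly treated mice. Among arrays of lower background the difference with flaxseed was -0.0810 in unirradiated mice (2 against 4) and -0.0454 in irradiated mice (3 against 1), and among those of higher background -0.395 (3 against 1) and -0.108 (2 against 4). Over all 9600 clones the diet and radiation fold changes correlated with r = -0.349, a relation across clones, below all 99 relabellings of diet within irradiation, which ranged from -0.293 to 0.262. Relabelling mixes the noise of the groups, so it does not carry the unequal noise of the real groups. The expected share of that noise in the covariance was 20.9%, and r without this share was not set against the relabellings.

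Unequal noise argues for caution here, since mean residual variances were 0.138 in untreated, 0.186 in flaxseed-fed, 0.185 in irradiated and 0.136 in doubly treated mice, an order that gives a negative relation by itself. Its expected share was -0.00481 of a covariance of -0.0230, and the averaged difference of -0.155 came from clones called without the mouse they score, so that unequal noise is argued against as the whole source. In simulations without a diet effect but with these spreads, 7.5% of 40 runs gave an exact p under 0.05 for that score, against 20% for clones called with the mouse. The simulated noise was independent between clones. Its averaged difference had an SD of 0.00884, where the real diet coefficient had an SE of 0.047 without a covariate. The simulation thus lacks any noise that clones of an array share, and its rates allow no conclusion on the real p. The averaged difference was -0.173 with the membrane trend removed (exact permutation p = 0.000819), and its coefficient was -0.153 (SE 0.048) with the log2 median signal as a covariate, which argues against array brightness and the trend. Within each background level the difference was negative in both radiation groups, but it was not tested there, over groups of 1 to 4 mice. Background thus stays open for the size of the difference in either radiation group. A batch that the labels do not give was not tested, and the pattern stays a hypothesis that may reflect the diet.

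Mice 1 and 5 of the group given both treatments had the arrays of lowest residual spread, with SDs of 0.271 and 0.278 log2 units against 0.309 to 0.459 in the other 18.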
